A study of Mus musculus with 6 samples.

How the data were processed

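RNA abundance was measured on 6 one-colour Affymetrix arrays, 3 hybridised with RNA of untreated mouse embryonic stem (ES) cells and 3 with RNA of cells grown with vitamin C. Per the labels' protocols, total RNA was purified on columns with DNase digestion, amplified with a whole-transcriptome kit (Ovation Pico WTA) and labelled with biotin. The series' design text calls the replicates biological triplicates. The deposited values are on a log2 scale, which was inferred from their range, and RMA is the tool named in the submitters' processing notes. RMA in general corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set. The software, its version and the probe-set level of that step are not given in the sources used here. Differences of dim probe sets are in general compressed on arrays, and quantile normalization holds the distributions of the arrays close together, so a change shared by all genes would not be visible in these values. Array medians over all probe sets lay between 5.52 and 5.60. A value is a level relative to the other arrays for one probe set. Levels of different probe sets are not comparable, and the number of arrays limits the precision. No detection calls were used here, so whether a dim gene lay above background was not tested.

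The value table held 35557 probe sets. The platform annotation gave 1 gene symbol for 21789 probe sets and several symbols for 1621, and 12147 probe sets are unnamed here. Of the probe sets with 1 symbol, 21698 matched a mouse gene table (assembly GRCm38.p6, used only for names and for which genes neighbour each other) by gene ID, and 0 symbols changed. The tests covered 19938 genes. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays was used. Probe sets with several symbols were left out of the gene results. Gene positions from that table served only to order genes along the chromosomes, and no coordinates are printed. No column of the table lacked a sample.

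Groups came from the sample titles. Vitamin C was compared with untreated by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05, and every adjusted p of a single gene below is from this test unless another setting is named. Differences are means of log2 values, vitamin C minus untreated, with the moderated standard error (SE). The 22 gene lists were tested with camera from limma at its preset inter-gene correlation of 0.01 (two-sided, Benjamini-Hochberg over the 22 lists). They covered germline genes, Rhox, Xlr and Mage family genes, 2-cell-stage genes, naive and primed pluripotency genes, markers of trophectoderm, primitive endoderm, neuroectoderm, mesoderm and definitive endoderm, and fibroblasts, the DNA methylation and demethylation machinery, JmjC histone demethylases, prolyl and lysyl hydroxylases, hypoxia-inducible factor (HIF) targets, NRF2 targets and antioxidant enzymes, ascorbate transport and recycling, ATF4 and amino acid stress targets, p53 targets, cholesterol biosynthesis, interferon-stimulated genes, imprinted genes and cell cycle genes. Fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, was an alternative. The lists, the tests, the other settings to be tried and the rule for named genes were fixed before the data were examined. That rule took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, passing over predicted genes without an assigned name, up to 4 called members of each list with the smallest p, and 9 genes set in advance (Dazl, Sycp3, Pou5f1, Nanog, Tet1, Tet2, Dnmt1, Dnmt3a, Dnmt3b). Other list members named in the text were chosen after their values were seen.

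The tests were tested on simulated data for this comparison, with the means and spreads of the 19938 genes and 200 changed genes in each of 5 runs. Changes of 1.25-fold were called for 14.8% of the simulated genes, of 1.5-fold for 60.8%, of 2-fold for 91.2% and of 4-fold for 98.8%, and 3.77% of all calls were false. The real comparison called 2623 genes, and the Benjamini-Hochberg cutoff depends on the share of changed genes. The shares recovered with 200 changed genes need not hold for the real data. In 50 simulated sets of arrays, a list shifted by 0.3 was called in all 50, and 3 of 1100 tests of unshifted lists were false calls. The simulated genes varied independently of one another, so these rates do not show how often lists of correlated genes are called falsely. The arrays were treated as unpaired. Alternative settings changed the spread model, the normalization, the filter on dim genes, the handling of several probe sets, the array weights, the threshold, the set test and the arrays included. Figures were drawn with matplotlib 3.10.9.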

Results

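The series asked how vitamin C, given for 72 hours at 200 μg/ml as a phosphate ester of ascorbic acid, changes the transcripts of mouse ES cells. The cells carried an Oct4-GiP reporter and grew on gelatin in serum-free N2B27 medium with LIF and the kinase inhibitors PD0325901 and CHIR99021, a combination used to keep ES cells in a naive state. There were 3 untreated and 3 vitamin C arrays. The arrays of one group correlated with each other at 0.995 to 0.996 across the 19938 genes, and arrays of different groups correlated at 0.989 to 0.990. The first principal component held 57.2% of the variance and separated the groups without overlap.

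The largest rises with vitamin C included germline and Mage family genes, and the largest falls included HIF targets. The largest rise was that of Asz1, a germ-cell factor of the piRNA pathway, from a log2 signal of 4.17 ± 0.49 (SD, n = 3) to 7.63 ± 0.12 (SD, n = 3), a log2 difference of 3.46 ± 0.22 (SE, adjusted p = 0.000235). Next among named genes came the cancer-testis genes Magea5, 10.2-fold higher, and Magea6, 7.28-fold higher, and between them Pramel6 of the PRAME family, 9.55-fold higher, and Aspa, the aspartoacylase gene, 7.90-fold higher. The other 5 of the 10 largest rises among genes with an assigned name, for which 4 predicted genes were passed over, were Cyp2b23, a cytochrome P450 (6.90-fold), Wfdc15a (6.37-fold), Dcaf8l (5.70-fold), the reproductive homeobox gene Rhox13 (5.37-fold) and AA467197 (5.02-fold, adjusted p = 0.0544 in a test without moderation). The untreated means of Magea5 (3.74), Magea6 (3.28) and Dcaf8l (3.26) lay below the lower quartile of every array (3.99 or more). The folds and ranks of these genes therefore rest on dim values. For Asz1 the value of untreated replicate 3 (3.61) lay below that quartile too, so its fold rests in part on a dim value. The largest fall was that of Bnip3, a mitophagy receptor of the outer mitochondrial membrane, from 9.22 ± 0.014 (SD, n = 3) to 5.52 ± 0.081 (SD, n = 3), a 13.0-fold difference (adjusted p = 8.77e-07). Ndufa4l2, a mitochondrial protein induced in hypoxia, was 12.5-fold lower. Aldolase C (Aldoc) was 5.86-fold lower, and the lactate transporter Slc16a3 was 5.41-fold lower. Falls of about 3-fold were measured for Tspo2 (3.04-fold), Ndrg2 (3.02-fold), the imprinted growth regulator Phlda2 (2.94-fold), the phosphofructokinase Pfkl (2.92-fold), the glutathione S-transferase Gstm3 (2.87-fold) and triosephosphate isomerase, Tpi1 (2.85-fold).

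Of the 19938 genes, 2623 passed the limma test, 1147 of them higher and 1476 lower with vitamin C. At least 2-fold rises numbered 90 and at least 2-fold falls 47, while the median size of the called differences was 0.41 on the log2 scale. At least 4-fold rises numbered 18, and 4 genes fell at least 4-fold. The 3 arrays of each group did not overlap for 35.0% of all genes, where chance gives 10%. When each array was centred on its median, 866 genes were higher and 1830 lower. With the trend of the difference against mean signal subtracted, 1176 were higher and 1280 lower. When all probe sets were tested, 1044 probe sets were higher and 1070 lower, so the size of the excess of falls depends on the setting. Without untreated replicate 1, 2 or 3 the count was 1626, 1555 or 1550, and without vitamin C replicate 1, 2 or 3 it was 1483, 1721 or 1625, from fits with fewer arrays. Magea3, Magea5 and Magea6, Tuba3a and Tuba3b, and some Rhox genes have close copies with which probes can cross-hybridise, so their separate values are uncertain.

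**Figure D1:**
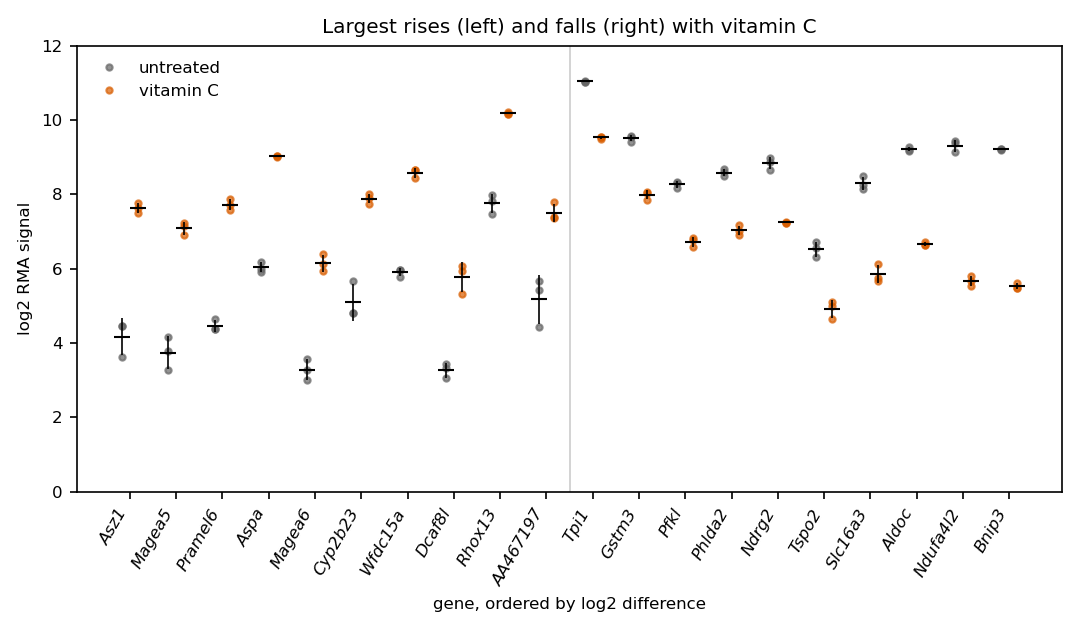
Log2 RMA signal (y axis) of the 10 genes with the largest rise and the 10 with the largest fall among the named genes (x axis, ordered by log2 difference), with a point per array, grey for untreated and orange for vitamin C, and black bars for the mean and SD of 3 arrays. The arrays of the groups do not overlap for any gene shown, from Asz1 (4.17 against 7.63) to Bnip3 (9.22 against 5.52).

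Targets of the hypoxia-inducible factors, the transcription factors of the response to low oxygen, were lower with vitamin C. Of 40 measured genes, 24 fell, 1 rose and 15 did not pass (27 fell and 1 rose when adjusted over the list alone), and the median log2 difference was -0.41. Camera placed the list below the other genes (adjusted p = 1.53e-15; adjusted p = 0.0133 with an estimated correlation). Besides Bnip3, Aldoc and Slc16a3, the glycolytic genes Tpi1, Pfkl, Pgk1 and Ldha fell by 1.51, 1.54, 1.10 and 1.28 on the log2 scale, with adjusted p-values from 2.53e-05 to 0.000143. Tpi1 and Pgk1 went from 11.04 ± 0.016 to 9.53 ± 0.031 and from 11.26 ± 0.019 to 10.16 ± 0.038 (SD, n = 3 each). Some genes outside glucose metabolism fell as well, among them Narf (-1.14), Ankrd37 (-1.34), the transcriptional repressor Bhlhe40 (-0.94) and the mitophagy receptor Bnip3l (-0.40). Others outside it, among them Adm, Hilpda, Mxi1 and Car9, did not pass. The 1 member that rose was Ddit4, an inhibitor of mTORC1 signalling that stress pathways other than hypoxia also induce, by 0.64 ± 0.07 (SE, adjusted p = 0.00168). Vegfa, which encodes an angiogenic growth factor, differed by -0.06 ± 0.07 (SE, adjusted p = 0.603), and hexokinase Hk2 by 0.01 ± 0.06 (SE, adjusted p = 0.926). Fibroblast markers differed in these arrays too, with 10 of 23 higher, 1 lower and 12 not passing (median 0.20; adjusted p = 0.159 with an estimated correlation).

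Germline genes, many of which are silenced by promoter methylation in somatic cells, were higher with vitamin C. Of 64 measured genes, 31 rose, 4 fell and 29 did not pass (32 rose and 5 fell when adjusted over the list alone), with a median log2 difference of 0.28. Camera placed the list above the other genes (adjusted p = 1.51e-09; adjusted p = 0.0133 with an estimated correlation). Dazl, an RNA-binding protein gene of germ cells, rose 4.62-fold, from 8.02 ± 0.11 to 10.23 ± 0.040 (SD, n = 3 each, adjusted p = 1.49e-05). Gtsf1, a cofactor of the piRNA pathway, rose 3.38-fold, Taf7l, which encodes a germ-cell subunit of the general transcription machinery, rose 3.25-fold, and the testis tubulin gene Tuba3b rose 4.68-fold. Of other members, Stra8, Sycp1 and Sycp3, genes of meiosis, rose, with Stra8 at 1.10 ± 0.10, Sycp1 at 1.10 ± 0.10 and Sycp3 at 0.43 ± 0.07 (log2 difference ± SE), the last from 9.12 ± 0.0040 (SD, n = 3). The 4 members that fell were Tdrd12 (-1.01), Stag3 (-0.71), Dmc1 (-0.57) and Syce2 (-0.44), genes of the piRNA pathway, meiotic cohesin, meiotic recombination and the synaptonemal complex. The germ-cell helicase gene Ddx4 differed by 0.13 ± 0.10 (SE, adjusted p = 0.438). The list was compiled from general knowledge with the study's interest in such genes known, so it is not independent evidence of their direction. In the same arrays 10 of 23 fibroblast markers rose, 1 fell and 12 did not pass (median 0.20), and camera's call of that list was lost at adjusted p = 0.159 with an estimated correlation.

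Of the X-linked Rhox, Xlr and Mage family genes, 16 of the 41 listed were measured by a probe set with 1 symbol. These were Rhox, Magea and Mageb genes with no Xlr gene among them, so the values of this list do not cover Xlr genes. Among them 9 rose, none fell and 7 did not pass (11 rose and none fell when adjusted over the list alone), and the median log2 difference was 0.57. Camera gave an adjusted p of 2.30e-08, and an adjusted p = 0.0230 with an estimated correlation. The rises were led by Magea5 (3.35), Magea6 (2.86), Rhox13 (2.42) and Magea3 (1.95). The untreated means of Magea3 (3.53), Magea5 and Magea6 lay below the lower quartile of every array. Rhox6 (0.38 ± 0.11 SE, adjusted p = 0.0607) and Rhox10 (0.51 ± 0.17 SE, adjusted p = 0.0940) did not pass. Beside this list too, 10 of 23 fibroblast markers rose (median 0.20; adjusted p = 0.159 with an estimated correlation).

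Of 30 measured genes of the machinery that writes and removes DNA methylation, 3 rose, 3 fell and 24 did not pass, where 13.2% of all genes tested passed (4 rose and 4 fell when adjusted over the list alone), and camera did not separate the list from other genes (adjusted p = 0.785). Tet1, the main 5-methylcytosine dioxygenase of ES cells, rose by 0.25 ± 0.06 (SE, adjusted p = 0.0321), a call that was lost with any 1 of the 6 arrays left out (adjusted p = 0.0601 to 0.0932), with arrays centred on their median (0.0758) and with all probe sets tested (0.0558). With 1 array left out its difference stayed between 0.23 and 0.27, and the trended and robust spread model gave an adjusted p of 0.000253. Tet2 differed by 0.18 ± 0.07 (SE, adjusted p = 0.143). Of the methyltransferases, Dnmt1 differed by -0.11 ± 0.06 (SE, adjusted p = 0.271), Dnmt3a by -0.21 ± 0.09 (SE, adjusted p = 0.168) and Dnmt3b by 0.16 ± 0.09 (SE, adjusted p = 0.308). The 95% confidence intervals of these 3 differences ran from -0.25 to 0.03, from -0.41 to -0.003 and from -0.06 to 0.37, so differences above 1.5-fold lie outside them. The DNA-damage gene Gadd45a rose by 0.44 ± 0.07 (SE), and its relative Gadd45b fell by 0.72 ± 0.14 (SE, adjusted p = 0.0153), the latter not passing without vitamin C replicate 1 (0.0557) or 3 (0.0530), with all probe sets (0.0518) or without moderation (0.0918). The other called members were Uhrf1 (-0.27 ± 0.07 SE, adjusted p = 0.0408) and Neil2 (-0.34), which fell, and Ung (0.31), which rose. Dnmt3l differed by -0.59 ± 0.17 (SE, adjusted p = 0.0567) and did not pass, with a 95% interval from -0.98 to -0.21.

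Among the prolyl and lysyl hydroxylases, 5 of 17 fell, none rose and 12 did not pass (6 fell and 1 rose when adjusted over the list alone). The collagen prolyl hydroxylase genes P4ha1 and P4ha2 fell by 1.07 and 0.41, the HIF prolyl hydroxylase gene Egln3 by 0.94 and the lysyl hydroxylase gene Plod1 by 0.53 on the log2 scale (Plod1 adjusted p = 0.0533 without moderation). P4ha1, P4ha2 and Egln3 were also members of the HIF target list. Camera did not separate this list (adjusted p = 0.294), and its median was 0.03 against a mean of -0.13, whereas fry found a directional fall (adjusted p = 0.000221). Of 22 JmjC histone demethylases, 2 rose, 3 fell and 17 did not pass (2 and 3 when adjusted over the list alone, camera adjusted p = 0.893), among them the Y-linked Kdm5d, higher by 0.88 ± 0.07 (SE), and Kdm4c, which fell by 0.55 ± 0.09 (SE, adjusted p = 0.0553 without moderation). For ascorbate transport and recycling, 1 of 15 genes rose, 3 fell and 11 did not pass (1 and 4 when adjusted over the list alone, camera adjusted p = 0.298). The gene that rose was Gsto1, a glutathione transferase with dehydroascorbate reductase activity, 2.51-fold higher (7.05 ± 0.12 to 8.38 ± 0.029, SD, n = 3 each, adjusted p = 0.000152). The glucose transporter gene Slc2a1 fell by 0.59 ± 0.07 (SE).

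Pou5f1, which encodes Oct4, differed by -0.12 ± 0.06 (SE, adjusted p = 0.235; 0.0125 with a trended and robust spread model), from 11.26 ± 0.022 to 11.14 ± 0.046 (SD, n = 3 each). Nanog rose by 0.29 ± 0.06 (SE, adjusted p = 0.0168), a call lost without untreated replicate 1 (0.0577) or 3 (0.0554) or without vitamin C replicate 1 (0.0542) or 3 (0.0530). With 1 array left out its difference stayed between 0.28 and 0.31, and the trended and robust spread model gave an adjusted p of 1.98e-06. In the naive pluripotency list 9 of 29 genes rose, 1 fell and 19 did not pass (12 rose and 1 fell when adjusted over the list alone). The rises were led by Eras (0.74) and Dppa2 (0.54), with Fbxo15 (0.39) and Tbx3 (0.35) also higher, and the member that fell was Tcl1 (-0.73). The list's call by camera (adjusted p = 0.00477) did not hold with the estimate of correlation (adjusted p = 0.243 with an estimated correlation). In the primed pluripotency list 7 of 24 genes rose, 1 fell and 16 did not pass (7 and 2 when adjusted over the list alone, camera adjusted p = 0.293, upward fry adjusted p = 0.0342), among them Foxd3 (0.84), Dusp6 (0.60) and Etv4 (0.42), which rose, and Cldn6 (-0.57), which fell. Dusp6 and Etv4 are transcribed in response to ERK signalling. Of the 2-cell-stage genes, 15 of the 36 listed were measured, with no Zscan4 gene among them, and 4 rose, 6 fell and 5 did not pass (5 and 6 when adjusted over the list alone). This list had a median of 0.24 and a mean of -0.13, camera gave an adjusted p near 1.00, and fry a downward adjusted p of 0.197. AF067061 (-0.86), Tcstv3 (-0.74) and Gm5662 (-0.77) fell and Ddit4l (0.70) rose. Without moderation the calls of Tcl1 (0.0642), Dusp6 (0.0667) and Gm5662 (0.0758) were lost.

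Of 23 measured fibroblast markers 10 rose, 1 fell and 12 did not pass (11 rose and 1 fell when adjusted over the list alone). Smooth-muscle actin Acta2 rose 3.55-fold, from 5.68 ± 0.34 to 7.51 ± 0.086 (SD, n = 3 each), the collagen-crosslinking enzyme gene Lox 2.81-fold, decorin (Dcn) 2.09-fold and the actin-binding protein gene Tagln 2.04-fold. The fold of Lox rests on a dim untreated mean (3.61), below the lower quartile of every array. The list's call by camera (adjusted p = 6.15e-06) was lost with the estimated value (adjusted p = 0.159 with an estimated correlation). Of 25 primitive endoderm markers 6 rose, 1 fell and 18 did not pass (6 and 1 when adjusted over the list alone), among them the endocytic adaptor gene Dab2 (0.89), the matrix gene Sparc (0.43), Cited1 (0.45) and the transcription factor gene Gata6 (0.39), and that call was likewise lost (camera adjusted p = 0.00477; adjusted p = 0.133 with an estimated correlation). The estimate for the primitive endoderm list was -0.015, below the preset of 0.01, so more correlation among its genes does not account for that loss. Camera called none of the remaining 3 lineage lists. In trophectoderm 2 of 27 rose, 5 fell and 20 did not pass (2 and 5 when adjusted over the list alone, camera adjusted p = 0.257), and the simple-epithelial keratin gene Krt8 fell by 0.58 ± 0.08 (SE). In neuroectoderm 3 of 24 rose, 2 fell and 19 did not pass (3 and 2 when adjusted over the list alone, camera adjusted p = 0.195), with Fabp7 (1.24, adjusted p = 0.0643 without moderation) and Neurod1 (0.70) higher and Stmn2 (-0.57) lower. In mesoderm and definitive endoderm 1 of 23 fell, none rose and 22 did not pass (none passed when adjusted over the list alone, camera adjusted p = 0.893), namely Mesp2 (-0.44 ± 0.11 SE). The call of Mesp2 was lost without untreated replicate 1 (0.103) or 3 (0.0925) and without vitamin C replicate 1 (0.115) or 2 (0.100).

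In the ATF4 and amino acid stress list 10 of 27 genes rose, 2 fell and 15 did not pass (15 and 2 when adjusted over the list alone), with Chac1 (0.88), Atf5 (0.48) and Sesn2 (0.47) higher and Nupr1 (-0.53) lower. Of 23 p53 targets 7 rose, 1 fell and 15 did not pass (8 and 1 when adjusted over the list alone), with Ptpn14 (0.93), Perp (0.76) and Ckap2 (0.54) higher and the phospholipid transfer protein gene Pltp (-0.96) lower. Both calls by camera (adjusted p = 0.00103 and 0.00207) were lost, at adjusted p = 0.282 and adjusted p = 0.243 with an estimated correlation. Of 28 NRF2 targets and antioxidant enzymes 6 rose, 3 fell and 19 did not pass (8 and 4 when adjusted over the list alone, camera adjusted p = 0.531, upward fry adjusted p = 0.0178). The selenium-dependent glutathione peroxidase gene Gpx2 rose 3.27-fold, from 9.17 ± 0.14 to 10.88 ± 0.16 (SD, n = 3 each), while the glutathione S-transferase genes Gstm1 and Gstm2 fell by 0.58 and 0.77 on the log2 scale.

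Of 41 imprinted genes 8 rose, 3 fell and 30 did not pass (8 and 3 when adjusted over the list alone, camera adjusted p = 0.257, upward fry adjusted p = 0.00155). Igf2, a paternally expressed fetal growth factor, rose 4.53-fold, from 6.50 ± 0.14 to 8.68 ± 0.094 (SD, n = 3 each, adjusted p = 3.91e-05), and the maternally expressed neighbours Phlda2 and Slc22a18 fell by 1.55 and 0.56 on the log2 scale. In cholesterol biosynthesis 3 of 20 genes fell, none rose and 17 did not pass (5 fell and 1 rose when adjusted over the list alone, camera adjusted p = 0.531), namely Tm7sf2 (-0.71), Pmvk (-0.48) and Ebp (-0.42), the last not passing without untreated replicate 2 (0.0637) or 3 (0.0591) or vitamin C replicate 1 (0.0670) or 3 (0.0642). Among interferon-stimulated genes 2 of 29 rose, 3 fell and 24 did not pass (2 and 4 when adjusted over the list alone, camera adjusted p = 0.606), with Ifi27 (0.61) higher and Ifi35 (-0.66) and Ifitm1 (-0.56) lower. Without moderation Ifi27 (0.0643) and Ifi35 (0.0705) did not pass. Among cell cycle genes 4 of 33 rose, 5 fell and 24 did not pass (4 and 6 when adjusted over the list alone, camera adjusted p = 0.357), with the growth-control genes Ccnd1 (0.58), Myc (0.60) and Mycn (0.33) higher and the topoisomerase gene Top2a (-0.38) lower (0.0772 for Top2a with the mean of its probe sets). In all, camera called 8 of the 22 lists, 7 up and 1 down, and 3 with an estimated correlation.

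**Figure D2:**
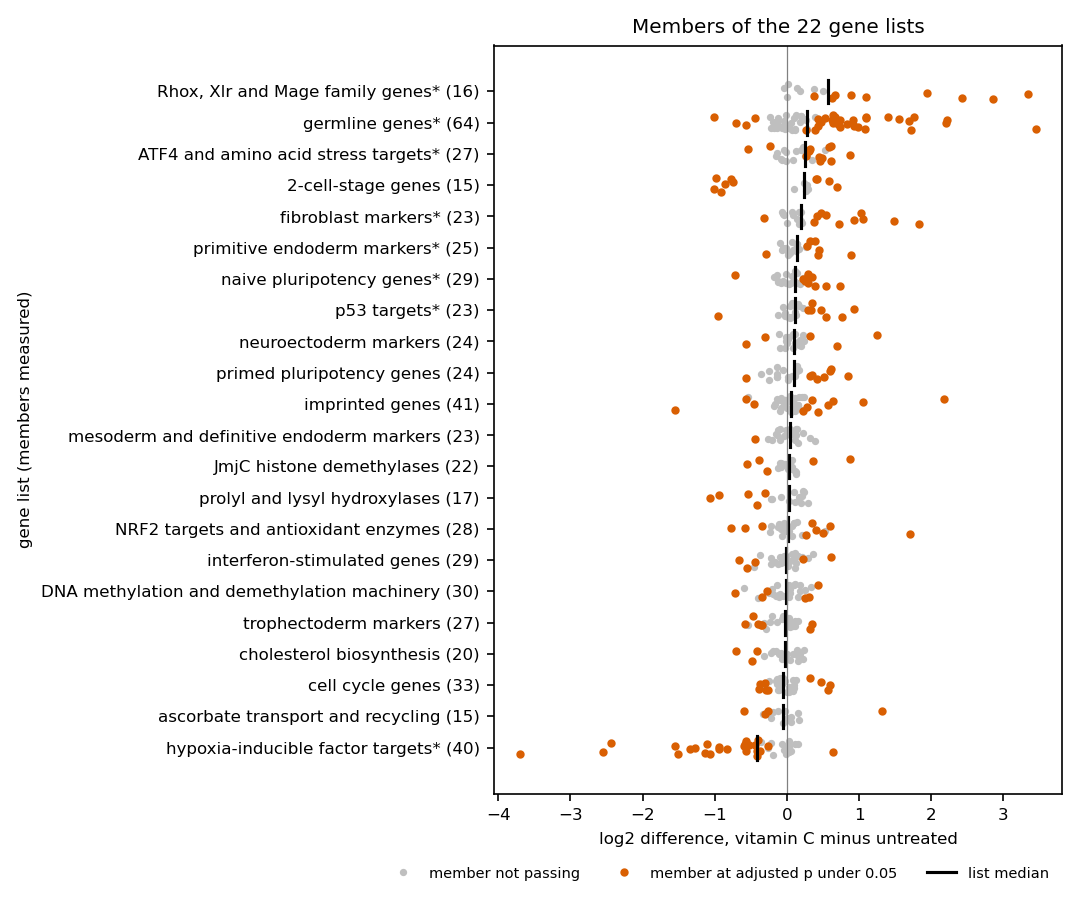
Log2 difference, vitamin C minus untreated (x axis), of every measured member of the 22 gene lists (y axis, with the number measured), orange for members that passed the limma test at an adjusted p under 0.05 and grey for others, with a black bar at the list median and an asterisk where camera called the list. HIF targets have the lowest median (-0.41) and the Rhox, Xlr and Mage list, in which no Xlr gene was measured, the highest (0.57).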

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

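The tests in this part that weigh the falls of HIF targets, the rises of fibroblast markers and the Y-linked genes were chosen after those results were seen, while the counts over other splits of the arrays were chosen before. Groups of 3 arrays were not tested for outlying arrays. Probe sets that name no single gene also carried differences. With all probe sets tested by limma, 397 of 12147 probe sets without a symbol passed (246 higher and 151 lower), as did 150 of 1621 with several symbols (115 higher and 35 lower).

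For the 10 ways to split the 6 arrays into 3 and 3, the real split was the 1 with a result as large. It called 2623 genes against at most 0 in another split, and 8 gene lists against at most 5. The germline list reached a -log10 p of 9.86 against at most 2.51. With 10 splits a share under 0.05 cannot be reached. Each of the other splits also held arrays of both groups on both sides. The difference between the groups then adds to the spread within a side, so low gene counts there follow from the design. Those sides were uneven mixtures of the groups, so part of the difference stayed between them. Their list calls and germline p-values are therefore no baseline free of the effect.

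HIF targets fell (24 of 40, median -0.41). A trend of the difference with signal strength is argued against by the list median of -0.41 after that trend was subtracted (95% interval over genes -0.57 to -0.29). A fall of glucose-use transcripts alone is argued against by the median of -0.39 among the 23 members outside glucose use (interval -0.57 to -0.036). Lower Hif1a mRNA is argued against by a Hif1a difference of 0.29 ± 0.06 (SE, limma adjusted p = 0.0180). Lower HIF activity with vitamin C, a cofactor of the HIF prolyl hydroxylases, may underlie the fall and stays a hypothesis, since HIF protein was not measured in these arrays.

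Of 23 fibroblast markers 10 rose, 1 fell and 12 did not pass (median 0.20), and camera's call of the list was lost at adjusted p = 0.159 with an estimated correlation. The signal trend is argued against by a median of 0.16 after its subtraction (interval 0.10 to 0.49). Fibroblast-like cells among the treated cells could account for part of the rise. Of the 7 collagen genes on the list 3 rose, Col1a1 (0.55), Col1a2 (0.47) and Col3a1 (0.37), while Col5a2 (0.20, adjusted p = 0.0629), Col5a1 (adjusted p = 1.00), Col6a1 (-0.05) and Col6a2 (-0.07) did not pass, so admixed cells and a change within the ES cells cannot be told apart here. Vim and Fn1, in general abundant in fibroblasts, differed by 0.10 and -0.04, and neither passed. Their untreated means were already 10.14 and 10.28, so a small share of added cells need not change them visibly. These 2 genes therefore do not decide the question.

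Some Y-linked genes rose, Uba1y by 1.24 ± 0.12, Zfy1 by 1.23 ± 0.16, Kdm5d by 0.88 ± 0.07 and Usp9y by 0.64 ± 0.14 (SE), while Eif2s3y (0.03), Uty (-0.08) and Zfy2 (0.09) did not pass. More cells with a Y chromosome are argued against by Eif2s3y and Uty, whose larger upper 95% bound of 0.21 lies below the lower bound of 0.72 for Kdm5d. Signal from the X-linked copies of Kdm5d, Zfy1 and Usp9y is argued against by the largest upper bound of those copies, 0.31. For Usp9y the margin is narrow, since its lower bound was 0.32, at dim mean signals of 3.33 (untreated) and 3.97 (vitamin C). The X-linked copy of Uba1y was not tested. No biological explanation was tested.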

How the results depend on the processing

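The setting with the signal trend removed and the germline list without near-identical copies were added after the data were seen, and where no reason is given the cause was not tested. The number of genes changed (2623, with 1147 higher and 1476 lower) was 4151 (1731 and 2420) with a trended and robust spread model and 1545 (667 and 878) without moderation. By construction it fell with stricter thresholds, to 617 (325 and 292) with a 1.5-fold minimum and 901 (405 and 496) at an adjusted p under 0.01. Above the median signal 3552 genes were called (1312 higher and 2240 lower). Leaving out 1 array, which leaves fewer arrays, gave 1483 to 1721 genes (663 to 733 higher, 820 to 988 lower). With the replicate number as a replicate block the count was 1723 (763 and 960). The numbers do not establish a pairing: deviations of same-numbered arrays correlated at 0.052, 0.0096 and -0.024, and 3 of 6 arrays correlated best with their own number. Gene lists called numbered 8 in every setting run except 3 with an estimated inter-gene correlation and 12 with fry, and 8 to 8 with 1 array left out. The estimate was -0.0072 for germline genes, -0.057 for the Rhox, Xlr and Mage list, -0.015 for primitive endoderm markers and 0.0090 for HIF targets. These lie below the preset of 0.01, so more correlation does not account for the larger adjusted p-values of these lists in that setting. A call lost in that setting is therefore not by itself evidence of correlation among the genes of a list. For fibroblast markers (0.091) and ATF4 targets (0.11) the estimate lay above the preset. How much of the loss of their calls this accounts for was not tested. The germline list stayed up at an adjusted p from 2.34e-11 to 0.0133 over its settings, with 5.77e-10 to 7.93e-09 when 1 array was left out. The direction turned for lists that did not pass either way. For 2-cell-stage genes this gave adjusted p-values of 0.860 (trended spread model), 0.995 (above the 25th percentile), 0.881 (mean of probe sets), 0.860 (replicate block), 0.197 (fry) and 0.993 (trend removed). For mesoderm and definitive endoderm they were 0.851 (quantile-normalized again), 0.679 (above the median signal) and 0.840 (trend removed). For the DNA methylation machinery they were 0.412 (above the median signal) and 0.957 (trend removed), and for cholesterol biosynthesis 0.978 and 0.993 in those settings. With 1 array left out, adjusted p-values over both directions ran from 0.708 to 1.00 for 2-cell-stage genes, from 0.406 to 0.989 for mesoderm and definitive endoderm and from 0.570 to 0.989 for JmjC demethylases. The direction turned without untreated 1 (0.949) and vitamin C 2 (0.708) and 3 (0.974) for the first list, without untreated 2 (0.977) and 3 (0.695) and vitamin C 1 (0.898) for the second, and without untreated 1 (0.969) and vitamin C 2 (0.834) for the third. Of 98 named genes called, 74 kept the call in every setting run, 24 lost it in at least 1, and 0 turned direction. The filters on dim genes left some named genes untested, among them Lox, Dcaf8l and Magea3.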

Other observations

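The test in this part was chosen after the data were seen, as were the genes named. Of 16 measured Pram genes 4 rose and 1 fell by limma, with Pramel12 3.35-fold higher (adjusted p = 0.000121), Pramel7 1.61-fold higher and Pramel19 1.53-fold lower. Of 19 Nlrp genes 3 rose and 1 fell, with Nlrp4c 2.95-fold higher and Nlrp4a 1.52-fold lower. These families hold close copies, so single values are uncertain. Among metallothioneins, Mt4 fell by 1.16 ± 0.07 (SE, adjusted p = 0.000152), while Mt1 and Mt2 differed by 0.08 and 0.10 and did not pass. Of the HIF subunit genes and regulators looked at, Hif3a (-0.95), Egln3 (-0.94) and Vhl (-0.38) fell and Hif1a (0.29) rose, while Epas1 (0.11), Egln1 (-0.22), Egln2 (0.21) and Hif1an (0.10) did not pass. Of single genes outside the lists, Ccn1 rose by 1.44 ± 0.08, Myl9 by 0.93 ± 0.11 and Cald1 by 0.58 ± 0.06 (SE), and Lgals1 fell by 0.50 ± 0.09 (SE).

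Risen genes lay next to one another more often than in most random sets. Of 1146 risen genes with a known place, 161 had a risen neighbour of another name stem, where 1000 random sets gave 126 on average and 169 at most, and 5 were as large (permutation p = 0.00599). Of 1476 fallen genes 309 had such a neighbour, against 232 on average and 295 at most (permutation p = 0.000999, the smallest that 1000 sets can give). What such neighbours have in common was not tested.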
